A study of Mus musculus with 18 samples.

How the data were processed

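The series holds 18 RNA libraries from bone-marrow-derived macrophages of wild-type C57BL/6J mice, in 6 groups of 3 set by the in vivo arm (PBS, 1xLPS, 4xLPS) and the in vitro condition (unstimulated or LPS). Per the labels' protocols, cells were grown in F12 DMEM with fetal bovine serum, total RNA was purified on RNeasy columns, poly(A) RNA was selected from 500 ng with Dynabeads, and libraries were made with an Ion Total RNA-seq kit and sequenced on an Ion Proton. Torrent Suite 5.12, TopHat2 followed by Bowtie2, the mouse build mm10 and Cufflinks are named per the labels and the submitters' processing notes. The program that counted reads per gene, the gene annotation and the strand setting are not given in the sources used here. Genes with near-identical copies or overlapping exons are therefore described as uncertain where they are named.

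The deposited workbook has a sheet whose name speaks of RPM. Its values are whole numbers whose sums differ between libraries (the lowest and highest were 9296453 and 54050622), so they were taken as raw counts of reads per gene symbol, as deposited by the authors, with no normalization. The design written before the data were examined planned limma for RPM values and edgeR's quasi-likelihood test if the table held raw counts, and the second was used. The named genes, gene lists, tests and the first set of alternatives were also fixed before the data were examined. A second sheet holds the authors' verdicts in words on 9 DESeq2 comparisons, which were copied and not recomputed from.

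Libraries were grouped by title. The treatment tag exchanges PBS and 4xLPS for 12 of the 18 libraries. The titles match the series design text and the arm in each column name of the count table. Each column also carries a sample number, and in 18 of 18 columns the tag of the sample with that number names the arm in the column name, so the tags follow the column order of the table. No column was left unused. Under the tags of the same-titled samples, the same fits hold with PBS and 4xLPS exchanged. Joined by sample number, tag and column name give the same arm, and nothing is exchanged. Between arms, the deviations of same-numbered libraries from their group means correlated with r = 0.60, 0.21 and 0.38 for PBS_NO and 4xLPS_NO, while each of the other 5 comparisons had a number under 0.1. The labels do not say what a number marks.

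Genes with at least 1 CPM in at least 3 of the 18 libraries were kept, which left 14158 of 43280 symbols. Counts were scaled by TMM and fitted with edgeR (version 4.0.16, glmQLFit and glmQLFTest) with 1 mean per group over all 18 libraries, no block and 12 residual degrees of freedom (median prior degrees of freedom 5.95, biological coefficient of variation 23.9%). The 12 contrasts were the LPS response of each arm, the 3 comparisons between arms in each in vitro condition and the 3 differences of LPS response. P-values were adjusted by Benjamini-Hochberg within a contrast and genes with an adjusted p under 0.05 were called. CPM values are TMM-scaled. A gene at 0 in a whole group was given a floor of 3 counts over that group.

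The 28 gene lists held 541 entries, all matched to the table, 4 of them under an older symbol (Irg1 for Acod1 among the genes named). They covered inflammatory cytokines, type I interferon, interferon gamma, negative feedback, LPS sensing, MHC class I and II, alternative activation, glycolysis, the tricarboxylic acid cycle, the respiratory chain, cholesterol biosynthesis and efflux, the cell cycle, oxidative stress, macrophage identity, lysosome, immediate early genes, ribosomal proteins, mitochondrially encoded transcripts, and markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells, erythroid cells, stromal cells and megakaryocytes. Lists with more than 1 tested gene (27) were tested with camera of limma (3.58.1) at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. The latter is the stricter test, and between arms it kept few calls.

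Genes named in the text were taken by rule. In each contrast these were up to 10 called genes that rose and 10 that fell with the largest fold change, with groups that did not overlap and a mean of at least 5 CPM in the higher group, leaving out predicted genes and pseudogenes. To these were added a panel of 12 genes in every contrast and, in each described list, up to 4 called genes by p and up to 2 not called by mean level. Irx3 and Adamts12 were named in addition, and 4 genes that the rule took are not reported here. Positions are from the GENCODE M21 annotation of GRCm38 (mm10), in which 91.2% of the symbols (39469) were found.

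The procedure was tested on counts simulated for 4xLPS against PBS, LPS-stimulated, over 14158 genes. It recovered 9 of 67 genes changed 1.5-fold (13.4%), 43 of 67 changed 2-fold (64.2%) and 64 of 66 changed 4-fold (97.0%), with 8 false calls (6.45% of the calls). The changed genes were taken from those with a mean of at least 5 CPM, and each gene was drawn independently. These rates therefore need not hold for genes nearer the filter or for libraries that share structure across genes. Replicate libraries differed by more than sampling noise in every group (lowest chi-square per degree of freedom 6.31), so no 2 were taken as the same library. This does not show that they are independent. Alternatives were other scalings (size factors of DESeq2, quantile normalization, none), pseudocounts, filters, dispersion settings, limma, DESeq2 (1.42.0), replicate numbers as a block, only the compared groups, and each library left out in turn. Voom with sample weights, leaving out 2 libraries, a stromal covariate and offsets on GC content were added after seeing the data. Calculations used R 4.3.3, Python 3.11.15 and matplotlib 3.10.9.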

Results

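Messenger RNA was profiled in bone-marrow-derived macrophages, phagocytes grown in culture from marrow precursors, of wild-type C57BL/6J mice. Lipopolysaccharide (LPS) is a bacterial cell wall product that macrophages sense through Toll-like receptor 4. The marrow came from mice that had been given PBS (the vehicle arm), LPS once (1xLPS) or LPS 4 times (4xLPS) in vivo, and the cultured cells were left unstimulated (NO) or stimulated with LPS in vitro (LPS). This gave 6 groups of 3 libraries, named below by arm and in vitro condition, such as PBS_LPS. The deposited table held whole-number read counts for 43280 gene symbols in 18 libraries. Total counts of libraries 1, 2 and 3 were 33340404, 26022517 and 26355647 in PBS_NO, 29720162, 51275987 and 9296453 in 1xLPS_NO, and 17798409, 22249109 and 19308305 in 4xLPS_NO. The stimulated libraries held 15347788, 23629185 and 54050622 in PBS_LPS, 29993426, 37895147 and 33236223 in 1xLPS_LPS, and 22170884, 25123133 and 46317127 in 4xLPS_LPS. A count of 0 therefore allowed a level of up to 0.0555 to 0.323 CPM, counts scaled to the library total, in a library, a floor of 3 counts that covers counting error only. At the filter used, 14158 genes were tested. Unless stated, values are CPM as mean ± SD or log2 fold changes ± SE with n = 3 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

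The arm of each library was taken from its title, which the series design text and the columns of the count table share. The treatment tag in the labels names the other arm of PBS and 4xLPS for 12 of the 18 libraries. With each column's arm taken from the tag of the same-titled sample, every direction given below for 4xLPS against PBS would turn round. The PBS and 4xLPS responses would exchange names. Each result for 1xLPS against PBS would then be one for 1xLPS against 4xLPS, and each for 4xLPS against 1xLPS one for PBS against 1xLPS. Taken instead from the sample whose number the column carries, the tag names the column's own arm in 18 of 18 columns. Read that way, no direction would turn. The in vitro condition is the same in both labels.

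The libraries separated by in vitro LPS on the 1st principal component of log2 CPM, which held 50.2% of the variance. On the 2nd, with 14.4%, 1xLPS_NO library 1 (score -66.6) and 1xLPS_LPS library 3 (-55.8) stood apart from the rest, followed by PBS_LPS library 3 (-25.4).

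**Figure D1:**
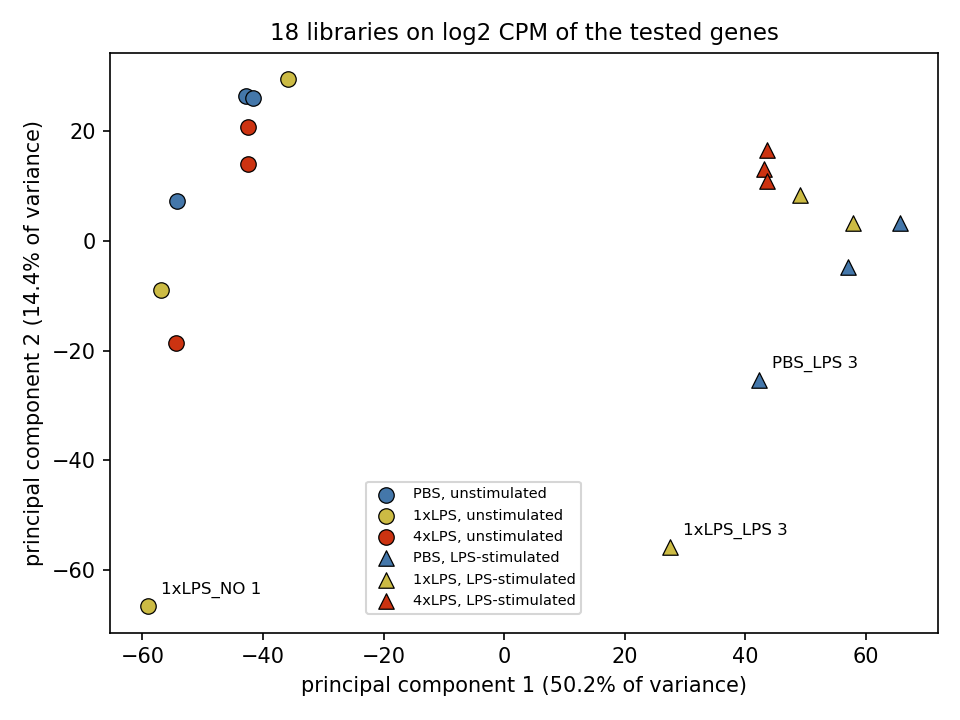
Scores of the 18 libraries on principal components 1 and 2 of log2 CPM over the tested genes, with the share of variance on each axis; color gives the in vivo arm and shape the in vitro condition (circles unstimulated, triangles LPS-stimulated). Unstimulated and stimulated libraries lie at opposite ends of component 1, and 1xLPS_NO library 1 and 1xLPS_LPS library 3 lie lowest on component 2.

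The first comparison asked how macrophages of vehicle-treated mice responded to LPS. Cytokine and chemokine genes were among the most strongly induced. Tnf, the cytokine tumour necrosis factor (mm10 chromosome 17, 35199381 to 35202007), rose from 22.3 ± 1.16 CPM in PBS_NO to 3653.5 ± 1232 CPM in PBS_LPS (log2 fold change 7.36 ± 0.35, adjusted p = 7.0e-11). Irg1 (Acod1 in current annotation; chromosome 14, 103046977 to 103056573), which makes the antibacterial metabolite itaconate, rose by 9.52 ± 0.35. The neutrophil-attracting chemokines Cxcl2 (9.83 ± 0.53) and Cxcl1 (9.28 ± 0.62), the T cell attractant Cxcl10 (9.02 ± 0.42), the guanylate-binding protein Gbp5 (8.98 ± 0.50) and the inducible nitric oxide synthase Nos2 (8.73 ± 0.57) were among the 1982 genes that rose. Among the 1597 that fell were Id1, an inhibitor of basic helix-loop-helix factors (-5.26 ± 0.44), the arrestin family member Arrdc3 (-5.04 ± 0.63) and the lysophosphatidic acid receptor Lpar6 (-4.43 ± 0.23). The cannabinoid receptor Cnr2 also fell (-3.66 ± 0.32). Cd300lf, an inhibitory receptor whose reads may be shared with near-identical copies, had -4.22 ± 0.43.

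Of 25 tested inflammatory cytokines and chemokines, 22 rose and 0 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 6.75, or 6.06 with the genes at 0 in a group set to their bound. Il1b (7.64 ± 0.57), Il6 (6.75 ± 1.06), the T cell attractant Ccl5 (7.04 ± 0.76) and the macrophage inflammatory proteins Ccl3 (6.89 ± 0.35) and Ccl4 (6.06 ± 0.32) were members. Osm was not called (-0.58 ± 0.24, adjusted p = 0.081). Il12b, a subunit of interleukins 12 and 23, had no count in PBS_NO and was at least 997-fold higher in PBS_LPS, taking 3 counts over the group as the floor. Among 28 genes of the type I interferon response 20 rose (22 adjusted over the list alone, median 1.70), such as Ifit1 (4.76 ± 0.32) and Rsad2 (5.13 ± 0.41), both antiviral effectors. Of 17 interferon gamma inducible genes 16 rose and 1 fell (also adjusted over the list alone, median 3.60), including the transcription factor Irf1 (4.22 ± 0.18) and Gbp2 (5.51 ± 0.42). As sets these 3 lists were shifted upward (camera adjusted p = 1.5e-33, 6.7e-14 and 2.9e-15), with adjusted p = 0.0073, 0.19 and 0.048 with an estimated correlation. The panel genes Il10, Ifnb1 and Arg1 stayed under the CPM filter and were not tested.

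**Figure D2:**
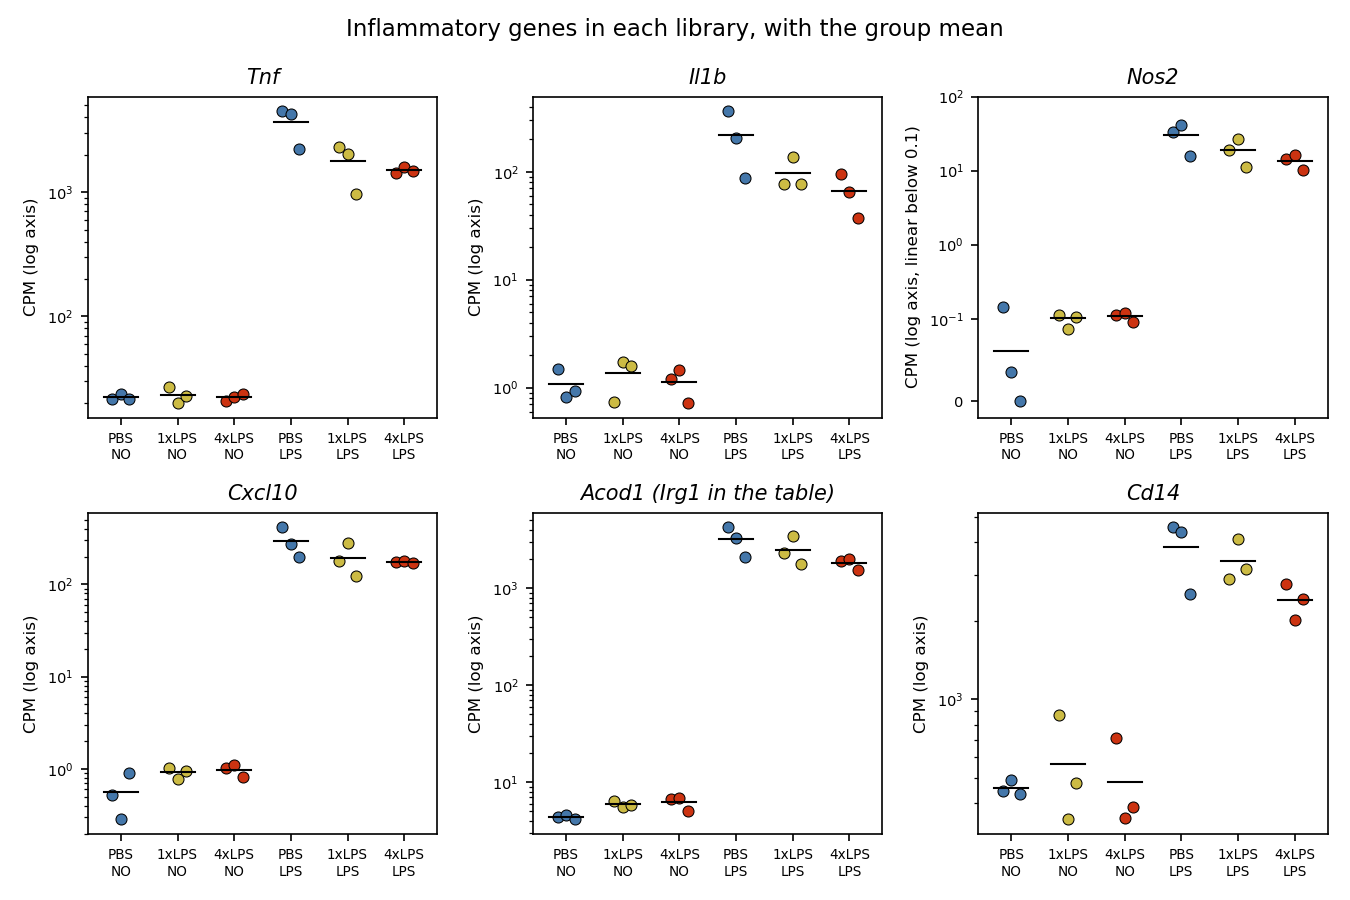
CPM of Tnf, Il1b, Nos2, Cxcl10, Acod1 (Irg1 in the count table) and Cd14 in each of the 18 libraries, by arm and in vitro condition, on log axes (Nos2 linear below 0.1); each point is a library and each line the mean of 3. The stimulated libraries lie above the unstimulated ones in every panel, and the 3 PBS_LPS libraries of Tnf lie above the 3 of 4xLPS_LPS.

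Regulators that restrain the response rose with it. Of 24 negative feedback and tolerance regulators 20 rose and 1 fell (21 and 1 adjusted over the list alone, median 1.93), including the cytokine signalling inhibitor Socs3 (4.62 ± 0.25) and the NF-kappaB inhibitors Nfkbie (3.58 ± 0.15) and Nfkbia (3.46 ± 0.19). In the list of LPS sensing and Toll-like receptor signalling, 18 of 31 rose (18 adjusted over the list alone, median 0.68), among them the LPS co-receptor Cd14 (3.06 ± 0.34), Tlr2 (2.77 ± 0.15) and the NF-kappaB subunits Relb (2.57 ± 0.15) and Nfkb2 (2.98 ± 0.17, with exons overlapping another gene). The LPS receptor Tlr4 itself gave 0.07 ± 0.22 (adjusted p = 0.84). Oxidative stress genes followed, with 15 of 18 risen (16 risen and 1 fallen adjusted over the list alone, median 1.35). Members that rose were the sulfiredoxin Srxn1 (2.50 ± 0.14), the mitochondrial superoxide dismutase Sod2 (3.01 ± 0.25), the autophagy receptor Sqstm1 (3.14 ± 0.18, overlapping another gene) and the cystine transporter Slc7a11 (6.11 ± 0.34, with near-identical copies). The 3 lists were shifted as sets (camera adjusted p = 1.5e-33, 1.2e-13 and 3.1e-16), with adjusted p = 0.00022, 0.0044 and 0.0022 with an estimated correlation.

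Antigen presentation lists had smaller medians. In MHC class I presentation 13 of 16 genes rose (14 adjusted over the list alone, median 0.89, camera adjusted p = 2.0e-05), and adjusted p = 0.26 with an estimated correlation. The peptide transporter subunit Tap2 (1.12 ± 0.21, overlapping another gene) and the proteasome activator Psme2 (1.90 ± 0.25, with near-identical copies) were among them. B2m gave 0.21 ± 0.23 (adjusted p = 0.54). In MHC class II presentation and costimulation, the 3 of 13 that rose (3 adjusted over the list alone) were the costimulatory molecules Cd40 (6.10 ± 0.39) and Icosl (4.22 ± 0.26) and the class II transactivator Ciita (1.60 ± 0.37). Cd74, the invariant chain, gave 0.24 ± 0.32 (adjusted p = 0.63). That list had a median of 0.26 (camera adjusted p = 0.023, and adjusted p = 0.48 with an estimated correlation). Its call was lost without PBS_LPS library 1 (adjusted p = 0.058). Of the dendritic cell markers 2 of 6 rose (2 adjusted over the list alone, median 0.24, camera adjusted p = 0.084), including Cd83 (2.76 ± 0.21).

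Metabolic, proliferative and identity genes split by member, and none of these lists was shifted as a set in the fit of all libraries. Within glycolysis 5 of 20 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.16, camera adjusted p = 0.36). The hexose transporters Slc2a6 (4.27 ± 0.34) and Slc2a1 (1.29 ± 0.20) and the phosphofructokinase Pfkp (1.23 ± 0.15) rose, and the regulatory enzyme Pfkfb3 fell (-1.13 ± 0.13). In the tricarboxylic acid cycle 5 of 23 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.0018). Pyruvate carboxylase Pcx rose (1.27 ± 0.30) and isocitrate dehydrogenase Idh1 fell (-0.90 ± 0.19). In the respiratory chain 0 of 32 nuclear-encoded genes changed (0 also adjusted over the list alone, median -0.015). Of 24 cholesterol biosynthesis genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.17). Dhcr7, which makes cholesterol in the last step, fell (-1.25 ± 0.21). The signs of the glycolysis, tricarboxylic acid cycle, respiratory chain, cholesterol biosynthesis and alternative activation medians turned under at least 1 other scaling. Cholesterol efflux genes had a median of -0.10, with 3 of 13 risen and 2 fallen (3 and 2 adjusted over the list alone). Soat1, which esterifies cholesterol, fell (-1.20 ± 0.19), and Apoe gave -0.65 ± 0.31 (adjusted p = 0.13). Cell cycle genes had a median of -0.25, with 1 of 28 risen and 4 fallen (1 and 3 adjusted over the list alone). The replication helicase subunits Mcm6 (-0.93 ± 0.19) and Mcm4 (-0.67 ± 0.14) fell and Mki67, which has near-identical copies, had 1.63 ± 0.19.

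Among 23 macrophage identity genes 5 rose and 8 fell (6 and 10 adjusted over the list alone, median -0.33, camera adjusted p = 0.078). The list was past the threshold without PBS_NO library 2 (-0.42, adjusted p = 0.027) or PBS_NO library 3 (-0.33, adjusted p = 0.043). The fractalkine receptor Cx3cr1 (-3.90 ± 0.38) and the efferocytosis receptor Mertk (-2.82 ± 0.22) fell, and the lineage factor Spi1 rose (1.56 ± 0.16). The lysozyme Lyz2, with a near-identical copy, gave -0.35 ± 0.26 (adjusted p = 0.36). Of 24 lysosome and phagocytosis genes 1 rose and 4 fell (1 and 3 adjusted over the list alone, median -0.18). Immediate early and dissociation stress genes went both ways, with 6 of 17 risen and 5 fallen (8 and 5 adjusted over the list alone, median 0.30). Fos, part of the AP-1 factor, fell (-2.07 ± 0.23). Alternative activation had 1 of 10 risen (1 adjusted over the list alone, median -0.05). This was the transcription factor Egr2 (0.66 ± 0.15, adjusted p = 0.0024), which limma on log2(CPM + 1) did not call (adjusted p = 0.076, in a range from 4.0e-05 to 0.076 over the alternatives).

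Markers of other marrow cell types went both ways. Of 10 stromal markers 3 rose (4 adjusted over the list alone, median 0.33), including the collagen Col3a1 (0.96 ± 0.23, adjusted p = 0.0039). The summed CPM of the list went from 1953 ± 179 in PBS_NO to 2607 ± 323 in PBS_LPS. In the megakaryocyte list 3 of 5 fell (3 adjusted over the list alone, median -0.88), among them the integrin Itgb3 (-0.88 ± 0.16), which macrophages also express. In the mast cell and basophil list 1 of 4 rose (1 adjusted over the list alone; median -0.28 but mean 0.29), the histidine decarboxylase Hdc (3.13 ± 0.57). Of 3 T and NK cell markers Ccl5, also a macrophage chemokine, rose and the interleukin 7 receptor Il7r fell (-1.24 ± 0.20). Adjusted over the list alone 1 of these rose and 2 fell (median -0.83 but mean 1.66). The 1 tested erythroid gene, the carbonic anhydrase Car2, rose (1.63 ± 0.44, adjusted p = 0.0097), but not without PBS_NO library 2 (adjusted p = 0.056) or PBS_LPS library 3 (0.066). Neutrophil markers (1 of 11 risen, 0 adjusted over the list alone, median 0.23) and B cell markers (0 of 4, 0 adjusted over the list alone, median -0.21) were not shifted as sets. Nor were mitochondrially encoded transcripts (0 of 13, 0 adjusted over the list alone, median -0.56) and ribosomal proteins (1 of 28 risen, 0 adjusted over the list alone, median 0.31).

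In all, 3579 genes changed in the PBS arm, 992 of them up and 847 down by at least 2-fold. DESeq2 called 4151 (2283 up and 1868 down) and voom 5464. Limma on log2(CPM + 1) without TMM scaling called 4001, of which 1223 rose and 2778 fell. The balance of directions thus differed between fits that differ in the test as well as the scaling. Without TMM the median of all tested genes lay at -0.21 in the PBS response, -0.10 in the 1xLPS response, 0.21 in 4xLPS_LPS over PBS_LPS and 0.19 in 4xLPS_LPS over 1xLPS_LPS. For the differences of response of 4xLPS from PBS and from 1xLPS it was 0.22 and 0.13. With TMM these medians lay near 0, and the changes given here are relative to them.

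Macrophages from LPS-treated mice also responded to LPS in vitro. In the 1xLPS arm 1705 genes rose and 1523 fell (1218 and 2197 by limma without TMM, 1875 and 1929 by DESeq2). In the 4xLPS arm 1506 rose and 1174 fell (1413 and 1257 by limma, 1555 and 1620 by DESeq2). These totals of 3228 and 2680 went to 1113 and 4891 with only the compared groups in the fit and to 4865 and 6687 with voom, and the 4xLPS total to 4065 without 1xLPS_NO library 1 and 1xLPS_LPS library 3. Tnf rose from 23.4 ± 3.56 to 1779 ± 714 CPM after 1xLPS (6.25 ± 0.33) and from 22.3 ± 1.5 to 1499.8 ± 95.3 CPM after 4xLPS (6.07 ± 0.33). Log2 fold changes in 1xLPS and 4xLPS were 8.70 ± 0.34 and 8.19 ± 0.33 for Irg1, 8.38 ± 0.50 and 9.03 ± 0.52 for Cxcl2, and 7.76 ± 0.40 and 7.48 ± 0.39 for Cxcl10. They were 7.46 ± 0.48 and 7.95 ± 0.51 for Gbp5, 6.15 ± 0.54 and 5.87 ± 0.55 for Il1b, and 2.58 ± 0.33 and 2.31 ± 0.33 for Cd14. The activation marker Cd69 rose in 1xLPS (6.38 ± 0.52). Id1 fell in both (-4.52 ± 0.41 and -5.18 ± 0.43). Lpar6 fell in 1xLPS (-4.13 ± 0.22) and the aspartate acetyltransferase Nat8l fell in 4xLPS (-3.26 ± 0.42).

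By list, cytokines and chemokines rose for 22 of 25 genes in 1xLPS (22 adjusted over the list alone, median 5.27, or 5.02 at the bound). In 4xLPS they rose for 20 of 25 (22 risen and 1 fallen adjusted over the list alone, median 4.97, or 4.26 at the bound). The medians in 1xLPS and 4xLPS were 0.89 and 0.94 for type I interferon and 3.34 and 3.12 for interferon gamma genes. With an estimated correlation these 2 lists were not past the threshold (adjusted p = 0.48 and 0.32 for type I interferon, 0.15 and 0.061 for interferon gamma). The cytokine list was past it (adjusted p = 0.014 and 0.0094 with an estimated correlation). So were negative feedback (medians 1.69 and 1.66, adjusted p = 0.00071 and 0.00019), LPS sensing (0.60 and 0.56, adjusted p = 0.014 and 0.012) and oxidative stress genes (1.10 and 1.04, adjusted p = 0.011 and 0.0068). MHC class I genes rose for 7 of 16 in 1xLPS (9 adjusted over the list alone, median 0.44, camera adjusted p = 0.018) and 7 of 16 in 4xLPS (9 adjusted over the list alone, median 0.64). They had adjusted p = 0.71 and 0.48 with an estimated correlation. The 1xLPS call was lost without 1xLPS_NO library 2 (adjusted p = 0.10) or 1xLPS_LPS library 2 (adjusted p = 0.092).

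Macrophage identity genes were shifted down as a set in 1xLPS (3 of 23 risen and 8 fallen, 3 and 8 adjusted over the list alone, median -0.20, camera adjusted p = 0.0092), though the median was 0.0059 without 1xLPS_LPS library 1. They were also shifted down in 4xLPS (2 risen and 10 fallen, median -0.42, camera adjusted p = 5.9e-05), with adjusted p = 0.62 and 0.31 with an estimated correlation. Lysosome genes were shifted down in 4xLPS (5 of 24 fallen, 6 adjusted over the list alone, median -0.36, camera adjusted p = 0.0018). Their adjusted p was 0.58 with an estimated correlation. Glycolysis in 4xLPS had 3 of 20 risen and 9 fallen (3 and 10 adjusted over the list alone, median -0.52) and was not past the set threshold (camera adjusted p = 0.069), except without 4xLPS_NO library 1 (-0.54, adjusted p = 0.046) or 4xLPS_NO library 2 (-0.57, adjusted p = 0.044). Slc2a6 rose (3.60 ± 0.34) and the lactate dehydrogenase Ldha, with near-identical copies, had -1.13 ± 0.25.

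The 1xLPS arm had 2 further set calls that hung on single libraries. Cell cycle genes were shifted down (1 of 28 risen and 4 fallen, also adjusted over the list alone, median -0.38, camera adjusted p = 0.031), except without 1xLPS_NO library 1 (adjusted p = 0.37), 1xLPS_LPS library 2 (0.16) or 1xLPS_LPS library 3 (0.098). Mitochondrially encoded transcripts were shifted up (3 of 13 risen, also adjusted over the list alone, median 0.75, camera adjusted p = 0.045), except without 1xLPS_NO library 1 (adjusted p = 0.056), 1xLPS_NO library 3 (0.26) or 1xLPS_LPS library 3 (0.48). Both had adjusted p = 0.91 with an estimated correlation.

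The responses of the arms, which share no libraries, overlapped. Between the PBS and 1xLPS arms 1234 genes rose in both (239 expected of independent lists of those sizes) and 1014 fell in both (172 expected), with 3 in opposite directions. Between PBS and 4xLPS 1226 rose in both (211 expected) and 918 fell in both (132 expected), with 0 opposite, and between 1xLPS and 4xLPS 1169 rose (181 expected) and 920 fell (126 expected), also with 0 opposite. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.82, 0.83 and 0.89.

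Whether in vivo LPS left a mark on unstimulated cells was asked by comparing the arms without in vitro LPS. Tnf lay close between the arms. It gave 0.07 ± 0.27 for 1xLPS against PBS and 0.01 ± 0.27 for 4xLPS against PBS (adjusted p = 0.93 and 1.0). Irg1 had higher means in the LPS arms without being called (0.46 ± 0.26 and 0.52 ± 0.26, adjusted p = 0.49 and 0.89). Irg1 was at 4.37 ± 0.21 CPM in PBS_NO, 6.00 ± 0.43 in 1xLPS_NO and 6.24 ± 0.99 in 4xLPS_NO. The cytokine list had medians of 0.16 in both comparisons (0.16 and 0.21 with genes at 0 set to the floor, which is no limit here) and was not shifted as a set. Stromal markers lay higher in both LPS arms. Their summed CPM was 1953 ± 179 in PBS_NO, 2804 ± 377 in 1xLPS_NO and 3678 ± 209 in 4xLPS_NO. The fibrillar collagen chains Col1a1 (chromosome 11, 94936224 to 94953042) and Col1a2 gave 1.04 ± 0.25 and 0.95 ± 0.23 for 4xLPS against PBS (adjusted p = 0.17 and 0.18). At the gene level no call was made by edgeR in any of the 3 comparisons in the planned fit. For 1xLPS against PBS the count of 0 stood beside 1669 genes at unadjusted p under 0.05, where chance gives 707.9. DESeq2 called 28, limma 0 and voom 556. For 4xLPS against PBS these were 849, 110, 0 and 817, and for 4xLPS against 1xLPS 1352, 37, 0 and 2005. Without 1xLPS_NO library 2 edgeR called 1593 genes for 1xLPS against PBS and 554 for 4xLPS against 1xLPS, and without 4xLPS_NO library 1 it called 1 for 4xLPS against PBS. Without the filter edgeR called 159 for 1xLPS against PBS, 130 for 4xLPS against PBS and 35 for 4xLPS against 1xLPS. With only the compared groups it called 236 for 4xLPS against PBS. Without 1xLPS_NO library 1 and 1xLPS_LPS library 3 it called 240 for that comparison and 61 for 4xLPS against 1xLPS.

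In 4xLPS_NO against PBS_NO the stromal list was shifted up as a set (median 0.79, camera adjusted p = 9.6e-19, and adjusted p = 0.035 with an estimated correlation). Of its 10 markers 10 were higher, 0 past the threshold over all genes and 8 adjusted over the list alone. Cell cycle genes were shifted up by less (median 0.35, camera adjusted p = 2.8e-08), beside the same higher stromal sum, with adjusted p = 0.63 with an estimated correlation. Of 28 genes 26 were higher, 0 called over all genes and 1 adjusted over the list alone, and the median turned to -0.069 with the stromal sum as a covariate. That sum did not overlap between PBS_NO (at most 2146) and 4xLPS_NO (at least 3480), so the fit does not separate stromal content from the arm. Cholesterol biosynthesis (20 of 24 higher, median 0.19, camera adjusted p = 0.0074) and glycolysis (17 of 20 higher, median 0.25, camera adjusted p = 0.028) were also shifted up. They had adjusted p = 0.65 and 0.91 with an estimated correlation and 0 genes called over all genes. The cholesterol call was lost without PBS_NO library 3 (adjusted p = 0.056) or 4xLPS_NO library 1 (0.18). The glycolysis call was lost without PBS_NO library 1 (0.058), PBS_NO library 2 (0.085) or 4xLPS_NO library 3 (0.11). Pcna, a replication clamp with near-identical copies, gave -0.47 ± 0.21 (adjusted p = 0.76).

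In 1xLPS_NO against PBS_NO the MHC class II list was shifted up (11 of 13 higher, 0 called over all genes and 7 adjusted over the list alone, median 0.61, camera adjusted p = 0.0011). Cd74 was at 561 ± 57.0 CPM in PBS_NO and 994 ± 168 CPM in 1xLPS_NO (0.83 ± 0.32, adjusted p = 0.37). The stromal list was also shifted up (9 of 10 higher, 3 adjusted over the list alone, median 0.52, camera adjusted p = 0.00027). Col1a1 gave 0.71 ± 0.25 (adjusted p = 0.36). Mitochondrially encoded transcripts were shifted down (13 of 13 lower, median -0.52, camera adjusted p = 0.00027), except without 1xLPS_NO library 3 (adjusted p = 0.098). Negative feedback genes (3 adjusted over the list alone, median 0.27, camera adjusted p = 0.034) lost their call without PBS_NO library 1 (0.10), PBS_NO library 3 (0.064) or 1xLPS_NO library 3 (0.068). Glycolysis (median 0.46, camera adjusted p = 0.0080) lost it without 1xLPS_NO library 1 (0.72), and the aldolase Aldoa gave 0.64 ± 0.23 (adjusted p = 0.36). Each of the 5 lists had adjusted p = 0.71 with an estimated correlation.

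Between 4xLPS_NO and 1xLPS_NO 3 lists held their calls when any 1 library was left out. MHC class I genes (14 of 16 lower, 2 fallen adjusted over the list alone, median -0.34, camera adjusted p = 0.00062) were shifted down. So were negative feedback genes (3 fallen adjusted over the list alone, median -0.15, camera adjusted p = 0.0044), and mitochondrially encoded transcripts were shifted up (13 of 13 higher, median 0.55, camera adjusted p = 5.6e-05). Another 6 lists were past the threshold but not without 1xLPS_NO library 2. These were MHC class II (median -0.55, adjusted p = 0.0031, then 0.073), with Cd74 at -0.78 ± 0.32, and interferon gamma (median -0.24, adjusted p = 0.021, then 0.44), with Irf1 at -0.58 ± 0.16 and Irf8 at -0.50 ± 0.17. The others were cholesterol biosynthesis (median 0.21), cell cycle (median 0.22), neutrophil markers (median 0.49) and stromal markers (median 0.29). Cholesterol biosynthesis also lost its call without 1xLPS_NO library 3 (0.23) or 4xLPS_NO library 1 (0.40). Stromal markers lost it without 4xLPS_NO library 1 (0.057) and interferon gamma without 4xLPS_NO library 3 (0.058). With an estimated correlation the interferon gamma list had adjusted p = 0.78 and each of the other 8 lists adjusted p = 0.58.

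The main question of the design, how in vivo LPS changed the stimulated state, was addressed by comparing the stimulated groups. In 4xLPS_LPS against PBS_LPS the genes that rose included matrix and growth factor genes. The growth factor Fgf7 (chromosome 2, 126034658 to 126091185) went from 8.60 ± 1.76 to 22.3 ± 2.35 CPM (1.37 ± 0.21, adjusted p = 0.035) and the collagen Col8a1 from 19.3 to 46.2 CPM (1.26 ± 0.21, adjusted p = 0.036). The collagen cross-linking enzyme Loxl2, which has near-identical copies, went from 48.0 to 99.8 CPM (1.06 ± 0.18, adjusted p = 0.036). Sertad4 (1.25 ± 0.21), the kinase Dmpk (1.17 ± 0.21), the water channel Aqp1 (0.99 ± 0.15) and Marveld1 (0.76 ± 0.14) also rose. The other 2 that rose, the homeobox factor Irx3 (1.92 ± 0.35) and the metalloprotease Adamts12 (1.69 ± 0.28), had mean levels below the 5 CPM set for named genes and were named after their values were seen. The 2 that fell were Ccrl2, an LPS-inducible chemokine-binding receptor (chromosome 9, 111054486 to 111057519; 335 ± 76.6 to 159 ± 27.5 CPM, -1.07 ± 0.19), and the ribosomal protein gene Rpl35. The latter has near-identical copies (162 ± 87.9 to 50.3 ± 4.93 CPM, -1.69 ± 0.31). The summed CPM of the stromal markers, which moved alongside, was 2607 ± 323 in PBS_LPS and 4964 ± 47.6 in 4xLPS_LPS.

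These 11 genes (9 up, 2 down) were all that edgeR called in the planned fit, beside 1963 at unadjusted p under 0.05. The count depended strongly on the tool, the setting and single libraries. EdgeR called 272 with only the compared groups, 248 without the filter and 580 without 1xLPS_NO library 1 and 1xLPS_LPS library 3. DESeq2 called 326 (139 up, 187 down) that included all 11, and limma 62 (59 up, 3 down) with 9 of them. Limma with quantile normalization called 10 (5 up, 5 down) with 5 of them, and voom with sample weights 1440 (654 up, 786 down) with all 11. Without PBS_LPS library 2 or any 1 of the 4xLPS_LPS libraries 1, 2 and 3 edgeR called 0 genes, without PBS_LPS library 1 it called 3, and without PBS_LPS library 3 it called 35. With the stromal sum as a covariate, a setting added after seeing the data, the count was 0, with wider errors. The changes stayed near their size for Ccrl2 (-1.20 ± 0.29), Rpl35 (-1.72 ± 0.45), Marveld1 (0.74 ± 0.21) and Aqp1 (0.87 ± 0.22). They were smaller for Adamts12 (1.37 ± 0.40), Fgf7 (0.95 ± 0.28), Irx3 (1.13 ± 0.44), Sertad4 (0.78 ± 0.27) and Dmpk (0.67 ± 0.27), and smaller still for Col8a1 (0.52 ± 0.20) and Loxl2 (0.43 ± 0.18). The sum did not overlap between PBS_LPS (at most 2936) and 4xLPS_LPS (at least 4910), so the covariate's slope came from the spread within groups. That spread was widest in 1xLPS_LPS (SD 1820, against at most 377 in the other groups). The covariate fits therefore do not separate stromal content from the arm.

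**Figure D3:**
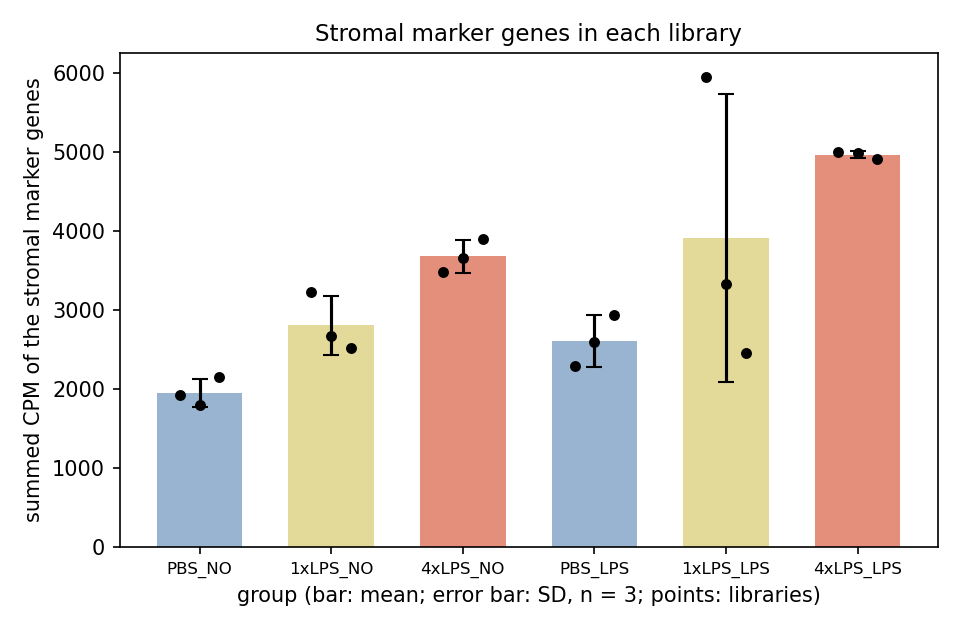
Summed CPM of the stromal marker genes in each library (points), with the group mean (bars) and SD (error bars, n = 3). The 4xLPS groups lie above the PBS groups in both in vitro conditions, and 1xLPS_LPS is spread by library 1 at 5949.5.

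In the planned fit no inflammatory gene given here but Ccrl2 was past the threshold over all genes. Cytokine genes nevertheless lay lower in 4xLPS_LPS. Tnf was at 3653.5 ± 1232 CPM in PBS_LPS and 1499.8 ± 95.3 CPM in 4xLPS_LPS (-1.28 ± 0.27, adjusted p = 0.094). Each PBS_LPS library lay above each 4xLPS_LPS library, and chance parts 3 libraries from 3 in one direction or the other for 10% of genes. Il1b (-1.72 ± 0.42, adjusted p = 0.14), Il6 (-2.28 ± 0.77, adjusted p = 0.21), Il12b (-1.70 ± 0.61, adjusted p = 0.24) and Cxcl2 (-1.21 ± 0.36, adjusted p = 0.17) had the same sign. So did Nos2 (-1.16 ± 0.35, adjusted p = 0.17), Irg1 (-0.81 ± 0.24, adjusted p = 0.17), Irf1 (-0.78 ± 0.16, adjusted p = 0.094) and Cd14 (-0.67 ± 0.31, adjusted p = 0.35), while Tlr4 gave 0.06 ± 0.22 (adjusted p = 0.92). Over 15 other settings, some chosen after the results were seen, Tnf and Irf1 were called in 5. Il1b, Cxcl2 and Irg1 were called in 4, Nos2 in 3, Il12b in 2, Cd14 in 1 and Tlr4 in 0. Il6 was called in 3 of 14. As a set the cytokine list was shifted down (22 of 25 lower, median -1.21, camera adjusted p = 3.5e-11), with adjusted p = 0.12 with an estimated correlation. Over all genes 0 of its members were called, and adjusted over the list alone 2 rose and 17 fell. Type I interferon genes were shifted down too (28 of 28 lower, 9 fallen adjusted over the list alone, median -0.65), with Rsad2 at -0.63 ± 0.34. So were interferon gamma genes (16 of 17 lower, 3 fallen adjusted over the list alone, median -0.58). These had adjusted p = 0.20 and 0.26 with an estimated correlation. Without PBS_LPS library 1 their medians were -0.34 and -0.19.

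With an estimated correlation 3 lists stayed past the threshold in this comparison. Negative feedback genes (22 of 24 lower, 10 fallen adjusted over the list alone, median -0.42, adjusted p = 0.041) included the NF-kappaB inhibitor Tnip1 (-0.59 ± 0.17, adjusted p = 0.16). LPS sensing genes (26 of 31 lower, 6 fallen adjusted over the list alone, median -0.32, adjusted p = 0.048) included the NF-kappaB subunit Rela (-0.43 ± 0.17, adjusted p = 0.27). Oxidative stress genes (18 of 18 lower, 6 fallen adjusted over the list alone, median -0.37, adjusted p = 0.041) included Sqstm1, which overlaps another gene (-0.54 ± 0.17, adjusted p = 0.18), and the heme oxygenase Hmox1 (-0.73 ± 0.25, adjusted p = 0.22).

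Other lists were shifted by the preset correlation alone. MHC class I (16 of 16 lower, 8 fallen adjusted over the list alone, median -0.42), MHC class II (12 of 13 lower, median -0.48) and glycolysis genes (17 of 20 lower, median -0.43) were shifted down, with adjusted p = 0.14, 0.26 and 0.14 with an estimated correlation. So were macrophage identity (18 of 23 lower, median -0.30), lysosome (21 of 24 lower, median -0.26) and ribosomal protein genes (27 of 28 lower, median -0.30), with adjusted p = 0.32, 0.32 and 0.54 with an estimated correlation. Stromal markers (10 of 10 higher, 8 risen adjusted over the list alone, median 0.72), cell cycle genes (26 of 28 higher, median 0.33) and mitochondrially encoded transcripts (13 of 13 higher, median 0.54) were shifted up. These had adjusted p = 0.12, 0.41 and 0.41 with an estimated correlation. With the stromal sum as a covariate 12 of the 18 lists of this comparison were called. The macrophage identity and MHC class II lists were then shifted up (medians 0.17 and 0.30). The stromal, cell cycle (-0.10), lysosome (0.12), ribosomal protein, tricarboxylic acid cycle and respiratory chain calls were lost, and the cytokine median was -1.67. As for single genes, this covariate does not separate stromal content from the arm. The class I gene H2-D1, with near-identical copies, gave -0.48 ± 0.17, Aldoa -0.62 ± 0.23 and Col1a1 0.79 ± 0.25 (adjusted p = 0.22, 0.25 and 0.18).

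A further 3 lists were past the preset threshold but not when 1 library was left out. The tricarboxylic acid cycle (median -0.14, but 0.11 without TMM, camera adjusted p = 0.025) lost its call without PBS_LPS library 3 (0.15), 4xLPS_LPS library 1 (0.060) or 4xLPS_LPS library 3 (0.054). The respiratory chain (median -0.17, but 0.076 without TMM, camera adjusted p = 0.031) lost it without PBS_LPS library 1 (0.23), PBS_LPS library 3 (0.13), 4xLPS_LPS library 1 (0.083) or 4xLPS_LPS library 3 (0.061). Dendritic markers (median -0.26, camera adjusted p = 0.021) lost it without 4xLPS_LPS library 3 (0.064). They had adjusted p = 0.54, 0.63 and 0.12 with an estimated correlation.

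**Figure D4:**
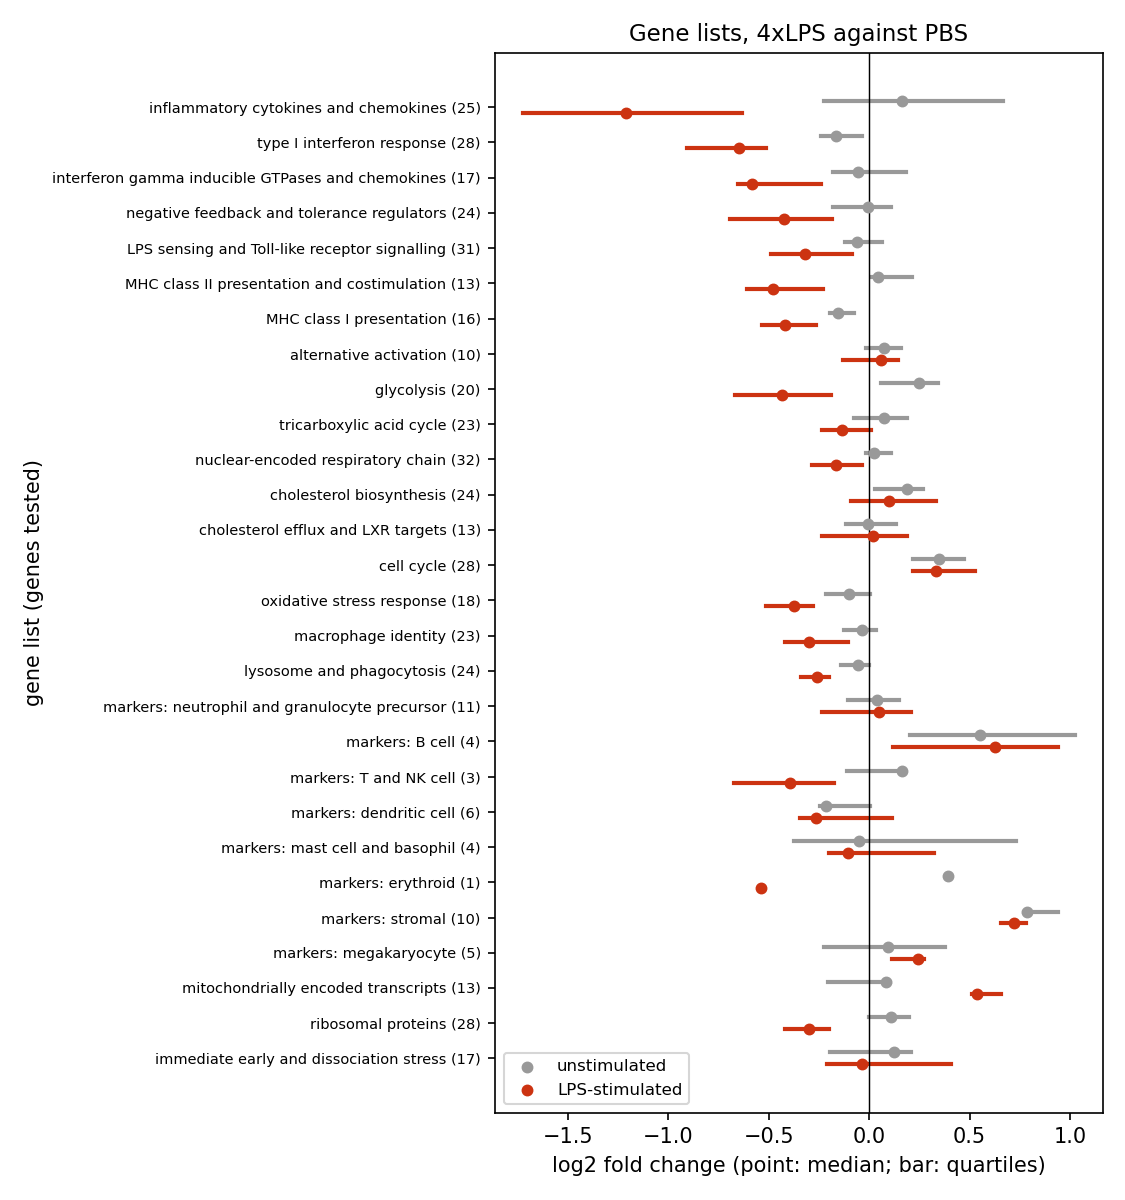
Median log2 fold change (points) with quartiles (bars) of the 28 gene lists for 4xLPS against PBS, unstimulated (gray) and LPS-stimulated (red), with the number of genes tested. Cytokines lie lowest when stimulated (-1.21) and stromal markers high in both (0.79 and 0.72); the stimulated medians of the tricarboxylic acid cycle and the respiratory chain turn positive without TMM scaling.

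In 1xLPS_LPS against PBS_LPS inflammatory genes also lay lower without passing the threshold. Tnf gave -1.04 ± 0.27, Il1b -1.17 ± 0.41, Il6 -1.99 ± 0.76, Cxcl2 -1.08 ± 0.36 and Irg1 -0.36 ± 0.24 (adjusted p = 0.54, 0.58, 0.59, 0.58 and 0.72). Cytokines (21 of 25 lower, 7 fallen adjusted over the list alone, median -0.95, camera adjusted p = 4.1e-11) and type I interferon genes (28 of 28 lower, median -0.58, camera adjusted p = 7.8e-12) were shifted down, with adjusted p = 0.20 and 0.22 with an estimated correlation. So were negative feedback (22 of 24 lower, median -0.22) and oxidative stress genes (16 of 18 lower, 1 fallen adjusted over the list alone, median -0.37), with adjusted p = 0.20 and 0.11 with an estimated correlation. Neutrophil markers were shifted down as well (9 of 11 lower, 5 fallen adjusted over the list alone, median -0.63, camera adjusted p = 0.00010, and adjusted p = 0.20 with an estimated correlation). The neutrophil granule protein gene Ngp went from 38.7 to 18.1 CPM (-1.10 ± 0.25, adjusted p = 0.48) and S100a9 gave -0.85 ± 0.33. Without PBS_LPS library 1 the cytokine and type I interferon medians were -0.56 and -0.26. EdgeR called 0 genes (1085 at unadjusted p under 0.05, 11 by DESeq2, 0 by limma, 0 by voom), and 1 without PBS_LPS library 1.

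In the same comparison 5 lists lost their calls with 1 library out. Interferon gamma (median -0.36) lost it without PBS_LPS library 1 (0.11) or 1xLPS_LPS library 3 (0.34), and LPS sensing (median -0.16) without PBS_LPS library 1 (0.081) or 1xLPS_LPS library 1 (0.17). MHC class I (median -0.21) lost it without PBS_LPS library 1 (0.28) or 1xLPS_LPS library 1 (0.089). Stromal markers (10 of 10 higher, median 0.49) lost it without 1xLPS_LPS library 1 (0.20) and mitochondrially encoded transcripts (13 of 13 higher, median 0.75) without 1xLPS_LPS library 3 (0.061). These had adjusted p = 0.41, 0.22, 0.41, 0.28 and 0.28 with an estimated correlation.

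Between 4xLPS_LPS and 1xLPS_LPS, Tnf (-0.25 ± 0.27, adjusted p = 0.81) and Irg1 (-0.45, adjusted p = 0.73) were not called. The cytokine (median -0.28), type I interferon (-0.084) and interferon gamma lists (-0.14) were not past the threshold, but this hung on single libraries. Without 1xLPS_LPS library 3 the 3 lists were shifted down (-0.57, -0.36 and -0.44, adjusted p = 1.7e-09, 1.2e-06 and 4.9e-07). Without 4xLPS_LPS library 2 the 2 interferon lists were shifted down (-0.26 for each, adjusted p = 0.047 and 0.012), and without 1xLPS_LPS library 2 the type I interferon list was shifted up (0.23, adjusted p = 0.032). MHC class II genes were shifted down (11 of 13 lower, 5 fallen adjusted over the list alone, median -0.76, camera adjusted p = 1.3e-06), with Cd74 at -1.21 ± 0.32 (adjusted p = 0.73). So were glycolysis (16 of 20 lower, median -0.36, camera adjusted p = 7.4e-05) and macrophage identity genes (20 of 23 lower, median -0.34, camera adjusted p = 0.00019). Cell cycle genes were shifted up (26 of 28 higher, 1 risen adjusted over the list alone, median 0.36, camera adjusted p = 3.0e-07). Each of these 4 lists had adjusted p = 0.30 with an estimated correlation. With the stromal sum as a covariate 7 lists were called in this comparison, against 12 without it. EdgeR called 0 genes (848 at unadjusted p under 0.05, 1 by DESeq2, 0 by limma, 1 by voom), and 2 without 1xLPS_LPS library 1.

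The other 8 list calls of this comparison each depended on a library, and with an estimated correlation these lists had adjusted p between 0.30 and 0.64. Negative feedback (median -0.14, but 0.064 without TMM) and MHC class I genes (median -0.19, but 0.037 without TMM) lost theirs without 1xLPS_LPS library 2 (0.24 and 0.34). LPS sensing (median -0.16, but 0.040 without TMM) lost its call without 1xLPS_LPS library 2 (0.24) or 4xLPS_LPS library 3 (0.062). The respiratory chain (median -0.18, but 0.021 without TMM) lost it without 1xLPS_LPS library 3 (0.17), 4xLPS_LPS library 1 (0.13) or 4xLPS_LPS library 3 (0.11). Lysosome genes (median -0.30, but 0.021 with quantile normalization) and ribosomal proteins (median -0.30) lost it without 1xLPS_LPS library 3 (0.17 and 0.56). Stromal markers (median 0.21) lost it without 1xLPS_LPS library 2 (0.23), 1xLPS_LPS library 3 (0.55) or 4xLPS_LPS library 3 (0.053), and neutrophil markers (median 0.73, with S100a9 at 0.90 ± 0.33) without 4xLPS_LPS library 3 (0.062).

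Whether the arms differed in the LPS response itself was tested by interaction terms. The cytokine list responded less in both LPS arms than in PBS (median differences -1.10 for 1xLPS and -1.12 for 4xLPS), with adjusted p = 0.34 and 0.32 with an estimated correlation. With genes at 0 set to the floor, which is no limit for a difference, the medians were -1.07 and -1.27. Without PBS_LPS library 1 the 4xLPS difference was -0.64. Tnf gave differences of -1.11 ± 0.38 and -1.29 ± 0.38 (adjusted p = 0.45 and 0.81), Cxcl10 -1.26 ± 0.52 and -1.54 ± 0.53 (0.56 and 0.81), Irf1 -0.88 ± 0.23 in 1xLPS (0.35) and Irg1 -1.33 ± 0.35 in 4xLPS (0.81). Part of the Cxcl10 and Irg1 differences came from higher mean unstimulated levels, though neither gene was called between unstimulated arms. Cxcl10 was at 0.92 ± 0.13 CPM in 1xLPS_NO and 0.98 ± 0.14 in 4xLPS_NO against 0.57 ± 0.31 in PBS_NO, all under 1 CPM. Irg1 was at 6.24 ± 0.99 CPM in 4xLPS_NO against 4.37 ± 0.21 in PBS_NO. Glycolysis responded less in 4xLPS than in PBS (19 of 20 genes lower, median -0.62, camera adjusted p = 3.1e-09, and adjusted p = 0.14 with an estimated correlation), with Aldoa at -0.77 ± 0.32 (adjusted p = 0.81). Between 4xLPS and 1xLPS the cytokine difference was -0.26 (-0.29 with the floor) and not past the threshold, except without 1xLPS_LPS library 3 (-0.50, adjusted p = 0.032). Tnf gave -0.18 ± 0.38 and Irg1 -0.51 ± 0.35. EdgeR called 0 genes in each of the 3 differences. For 1xLPS from PBS these stood beside 1154 genes at unadjusted p under 0.05, 34 by DESeq2, 0 by limma and 1 by voom, for 4xLPS from PBS beside 803, 6, 0 and 206, and for 4xLPS from 1xLPS beside 300, 0, 0 and 0. For the 1xLPS difference edgeR called 17 genes without PBS_LPS library 1 and 1 without 1xLPS_NO library 2.

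Across the tested genes, which are not independent replicates, the fold changes of 1xLPS and of 4xLPS against their shared PBS libraries correlated with r = 0.543 unstimulated and 0.644 stimulated. Simulated unchanged groups against shared simulated PBS libraries gave 0.485 and 0.519. Each gene was drawn independently there, so structure that genes share across libraries was missing and these values may be too low a reference. The same dispersion was used for every arm, although the within-group variance was 0.141 in PBS, 0.296 in 1xLPS and 0.101 in 4xLPS. That can put the reference off in the other direction. Without 1xLPS_NO library 1 r was 0.296 unstimulated, and without 1xLPS_LPS library 1 it was 0.380 stimulated, so r depended on single libraries. No unchanged groups were simulated with a library left out. The covariance was 0.0750 against a simulated 0.0555 unstimulated (difference 0.0195) and 0.116 against 0.0592 stimulated (difference 0.0573). With 3 libraries the controls could not be split, so part of the difference may come from the shared controls.

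The authors' deposited table gives a verdict in words for 9 comparisons, which its header ties to DESeq2. It lists the response to LPS of each arm as "Huge DE", 4xLPS against PBS as "Good DE" stimulated and "Small DE" unstimulated, and the other 4 comparisons between arms as "No DE". The DESeq2 counts computed here were 4151, 3804 and 3175 for the responses, 326 and 110 for 4xLPS against PBS, and 28, 37, 11 and 1 for the other 4.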

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

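Of the tests weighed here, that of a lower macrophage share was chosen only after the result was seen. The results of this part were singled out because the response of a gene list to LPS differed between 2 arms in a test of that difference itself, an interaction term (camera with the preset correlation). With an estimated correlation the lowest adjusted p among them was 0.14, so none passed by that stricter test. The arms rest on the titles. Under the tags of the same-titled samples the differences of 4xLPS from PBS would turn round. Those of 1xLPS from PBS would be from 4xLPS, and those of 4xLPS from 1xLPS would be of PBS from 1xLPS. Joined by sample number, the tags name the arms of the columns, and nothing would turn.

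For 1xLPS from PBS, the median difference of response was -1.10 for inflammatory cytokines and chemokines, -0.58 for type I interferon, -0.56 for interferon gamma, -0.49 for negative feedback and -0.24 for oxidative stress genes. It was 1.23 for mitochondrially encoded transcripts. These calls held when any 1 library was left out, but not their sizes. The mitochondrial median was 0.67 without 1xLPS_LPS library 3, interferon gamma -0.25 without the same library, type I interferon -0.32 without PBS_LPS library 1, and oxidative stress -0.12 without 1xLPS_NO library 1. LPS sensing (-0.13) lost its call without 1xLPS_NO library 2 (adjusted p = 0.092), PBS_LPS library 1 (0.11) or 1xLPS_LPS library 1 (0.10), MHC class I (-0.43) without PBS_LPS library 1 (0.083), and glycolysis (-0.39) without 1xLPS_NO library 1 (0.23). The tricarboxylic acid cycle (-0.17) lost it without PBS_NO library 2 (0.066), 1xLPS_NO library 1 (0.47), PBS_LPS library 3 (0.078), 1xLPS_LPS library 1 (0.19) or 1xLPS_LPS library 2 (0.14). Ribosomal proteins (-0.31) lost it without PBS_NO library 1 (0.20), 1xLPS_NO library 1 (0.13, where the median turned to 0.21), PBS_LPS library 1 (0.22), 1xLPS_LPS library 1 (0.70) or 1xLPS_LPS library 2 (0.35).

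For 4xLPS from PBS, the median difference was -1.12 for cytokines and chemokines, -0.57 for type I interferon, -0.41 for negative feedback, -0.51 for MHC class II, -0.62 for glycolysis, -0.32 for oxidative stress and -0.45 for ribosomal protein genes, and 0.50 for mitochondrially encoded transcripts. Without PBS_LPS library 1 it was -0.64 for cytokines and -0.15 for type I interferon, and without 4xLPS_NO library 1 -0.29 for MHC class II and -0.26 for ribosomal proteins. For LPS sensing it was -0.18 (but 0.033 without TMM) and for the tricarboxylic acid cycle -0.15 (but 0.12 without TMM). Interferon gamma genes (-0.50) lost their call without PBS_LPS library 1 (adjusted p = 0.10), MHC class I (-0.25) without 4xLPS_NO library 1 (0.061) or PBS_LPS library 1 (0.16), the respiratory chain (-0.18, but 0.051 without TMM) without 4xLPS_NO library 1 (0.33) or PBS_LPS library 1 (0.14), macrophage identity (-0.29) without 4xLPS_NO library 1 (0.050), and lysosome genes (-0.22, but 0.079 with quantile normalization) without 4xLPS_NO library 1 (0.050) or PBS_LPS library 3 (0.054).

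Between 4xLPS and 1xLPS, the differences were -0.23 for glycolysis, -0.22 for lysosome genes and -0.67 for mitochondrially encoded transcripts. Glycolysis lost its call without 1xLPS_NO library 2 (adjusted p = 0.66), 1xLPS_NO library 3 (0.17), 1xLPS_LPS library 3 (0.30) or 4xLPS_LPS library 2 (0.068), lysosome genes without 1xLPS_NO library 2 (0.26) or 1xLPS_LPS library 3 (0.82), and mitochondrially encoded transcripts without 1xLPS_LPS library 3 (0.13).

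The pattern weighed is the lower level of inflammatory cytokine genes in 4xLPS_LPS than in PBS_LPS (median -1.21). A lower share of macrophages alone would lower macrophage genes as far, but the lower quartile of the macrophage identity list was at -0.42, above the cytokine median. This argues against a lower share as the whole cause only. The identity list was itself lower (median -0.30) and some of its genes respond to LPS, so a share in part is left open. A single library does not account for it, since the highest median without any 1 of the 6 libraries was -1.05. Whether all LPS-induced genes responded less after 4 doses stayed open: the 883 genes that rose at least 2-fold in the 1xLPS arm, without the cytokine list, had a median of -0.20 (p = 0.223 with an estimated correlation), in the direction of a weaker response but small beside the spread of correlated genes. A change in the cells that the in vivo doses left behind may be the source, as a hypothesis, and it was not tested apart from the arms.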

How the results depend on the processing

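Voom with sample weights, leaving out 1xLPS_NO library 1 with 1xLPS_LPS library 3, the stromal covariate and the GC offsets were chosen only after the results were seen; the other alternatives were planned. Each LPS response had 1113 called genes or more under every setting, in an order of size that changed between settings. Counts between arms did not hold: 4xLPS against PBS stimulated had 11 called genes as planned and from 0 to 1440 in the alternatives. Apart from settings that test fewer or more genes or samples, the cause was not tested. Of the counts of genes changed, 141 stayed within 1.5 times of the planned value under other settings and 42 moved. Most comparisons between arms had a planned count of 0, and a 0 that stayed 0 was taken as stayed. The arms relabelled by the treatment tags, which only exchanges groups, were included too. The gene totals therefore do not measure how well calls between arms held. Of the counts of lists, 48 stayed and 18 moved.

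DESeq2 called 28 genes for 1xLPS against PBS, 110 for 4xLPS against PBS and 37 for 4xLPS against 1xLPS unstimulated, 11, 326 and 1 stimulated, and 34 and 6 for the differences of 1xLPS and 4xLPS from PBS. Without a filter edgeR called 159, 130 and 35 unstimulated, 93, 248 and 44 stimulated, and 144, 33 and 4 for the differences. Voom called 5464, 4865 and 6687 in the PBS, 1xLPS and 4xLPS responses, 556, 817 and 2005 unstimulated, 1440 for 4xLPS against PBS and 1 for 4xLPS against 1xLPS stimulated, and 1 and 206 for the differences from PBS. With only the compared groups the counts were 1113 in the 1xLPS response, 4891 in the 4xLPS response, and 236 and 272 for 4xLPS against PBS unstimulated and stimulated. Without the 2 libraries apart on component 2 they were 4065 in the 4xLPS response, 240 for 4xLPS against PBS and 61 for 4xLPS against 1xLPS unstimulated, and 580 for 4xLPS against PBS stimulated. For this last comparison limma called 62, or 20 and 90 with pseudocounts of 0.25 and 5, GC offsets gave 23, no abundance trend 4 and the stromal covariate 0, which called 1 gene for 1xLPS against PBS.

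With the stromal covariate 10 lists were called for 1xLPS against PBS, 10 for 4xLPS against PBS and 4 for 4xLPS against 1xLPS unstimulated, and 12 for 4xLPS against PBS (18 without it) and 7 for 4xLPS against 1xLPS stimulated; the macrophage identity median of 4xLPS against PBS stimulated turned to 0.17. Without the 2 libraries 8 lists were called for 1xLPS against PBS unstimulated and 5 for the difference of 4xLPS from 1xLPS. With an estimated correlation 5, 4 and 4 lists were called in the PBS, 1xLPS and 4xLPS responses, 1 and 3 for 4xLPS against PBS unstimulated and stimulated, and 0 in the 7 other contrasts. Over the 11 genes called in 4xLPS against PBS, stimulated, its r with 1xLPS against PBS was 0.976. These genes were chosen by 1 of the 2 comparisons, which share the PBS libraries, and no unchanged groups were simulated for that choice, so this r does not measure agreement.

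Leaving out 1 library at a time, the responses had 2691 to 3067, 2218 to 4253 and 1911 to 2093 genes in the PBS, 1xLPS and 4xLPS arms. Unstimulated comparisons had 0 to 1593 (without 1xLPS_NO library 2), 0 to 1 (4xLPS_NO library 1) and 0 to 554 (1xLPS_NO library 2), and stimulated ones 0 to 1 (PBS_LPS library 1), 0 to 35 (PBS_LPS library 3; 3 without library 1; 0 without library 2 or 4xLPS_LPS library 1, 2 or 3) and 0 to 2 (1xLPS_LPS library 1). The differences had 0 to 17 (PBS_LPS library 1; 1 without 1xLPS_NO library 2), 0 to 0 and 0 to 0. Lists called ranged, in the same order, from 7 to 9, 8 to 11, 9 to 11, 4 to 8, 3 to 6, 3 to 11, 7 to 14, 15 to 18, 9 to 14, 8 to 15, 11 to 16 and 1 to 10. Lists not called in the fit of all libraries were also called in some of these fits, and the medians of called lists between arms often moved by over 1.5 times. The agreement ranged from 0.296 to 0.665 unstimulated and 0.380 to 0.789 stimulated.

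Within an arm the replicate numbers did not mark libraries that deviate together. The correlation of the deviations of same-numbered libraries was -0.14, 0.06 and 0.02 in PBS, -0.26, 0.44 and -0.13 in 1xLPS and 0.16, -0.04 and 0.26 in 4xLPS, and not every library correlated best with its own number. With the replicate block the responses had 3162, 2793 and 2333 genes, 4xLPS against PBS stimulated had 12, and the other counts stayed at 0. For 4xLPS against PBS unstimulated, where same numbers did deviate together, the block left 0 genes and 4 lists called, as without it. That block gave each number an effect shared by all 18 libraries. It could not take up a pairing found in these groups alone, so its result does not test that pairing. Of the called genes named here, none reversed under any alternative. Depth may limit the call of genes near the filter, as the shallowest library, 1xLPS_NO library 3, held 9296453 counts, but this was not tested.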

Other observations

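All tests of this part but that of GC content and the splits of the libraries were chosen only after the results were seen.

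Stromal marker genes were higher in 4xLPS than in PBS libraries in both conditions (median 0.79 unstimulated and 0.72 stimulated). A lower macrophage share would raise the markers of every other cell type alike. For the other 7 cell types pooled, the lower quartile of the stromal markers lay at least 0.38 above the upper quartile of their markers in both conditions. Some of the pooled markers, such as Ccl5 and Itgb3, are also expressed by macrophages and need not rise in this way, so this cannot decide the question. Of the pooled types, 3 of 4 B cell markers were also higher in each condition, with medians of 0.55 unstimulated and 0.63 stimulated. Their summed CPM did not follow, at 225 ± 33.7 in PBS_NO and 232 ± 40.2 in 4xLPS_NO, and 134 ± 27.6 in PBS_LPS and 122 ± 6.93 in 4xLPS_LPS. As a set they were not past the threshold unstimulated (camera adjusted p = 0.068), but were without PBS_NO library 1 (0.035), PBS_NO library 3 (0.024), 4xLPS_NO library 2 (0.039) or 4xLPS_NO library 3 (0.017). More stromal cells in the 4xLPS cultures remains a candidate source, since the stromal markers moved by like amounts, with a ratio of SD to mean of their log2 fold changes of at most 0.389. A rise of these genes within the macrophages was not tested, and stromal cells would be a hypothesis found and tested on the same data. With the stromal sum as a covariate the cell cycle list went from 0.35 to -0.069 unstimulated and from 0.33 to -0.10 stimulated. The slope of that covariate rests on the spread within groups, widest in 1xLPS_LPS, so stromal content and the arm are not separated.

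The libraries of the 1xLPS groups spread more than the others (within-group variance of log2 CPM 0.296, against 0.141 in PBS and 0.101 in 4xLPS). GC content was argued against as the whole cause, because offsets on it removed 10.1% of the within-group variance of these groups. Depth of 1xLPS_NO library 1 and 1xLPS_LPS library 3 was argued against too, since 0 of the 2 lay outside the range of the total counts of the other 16. Along component 2 the gene loadings followed GC content (Spearman -0.428 over 13500 genes) and mean level (-0.320) more than length (0.118), across genes, which are not independent replicates. What sets these libraries apart stayed open, and no biological explanation was tested.

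Other splits of the same libraries were run for each count of genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone gave as many genes as the real count, 1 of 10, for the PBS response (3579, highest other 0), the 1xLPS response (3228, highest other 2661), the 4xLPS response (2680, highest other 0) and 4xLPS against PBS stimulated (11, highest other 0). For 1xLPS against PBS and 4xLPS against PBS unstimulated and 4xLPS against 1xLPS stimulated all 10 splits gave the real 0, for 1xLPS against PBS stimulated the highest other was 1, and for 4xLPS against 1xLPS unstimulated it was 1480. In each of the 3 differences of response all 25 splits gave at least the real 0, with highest others of 1360, 225 and 1. A real count of 0 fixes this outcome, so it says nothing about chance. The splits with 2661, 1480 and 1360 genes point to a structure of the libraries other than the groups. That of the 1xLPS response put 1xLPS_LPS libraries 1 and 2 with 1xLPS_NO library 2. The split with 225 genes put the 4xLPS_LPS with the PBS_NO libraries, which turns the difference of response into the difference of the arms over both conditions, so it follows the groups.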
